A study of Mus musculus with 14 samples.

How the data were processed

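The 14 arrays were 2-colour Agilent arrays read with Agilent Feature Extraction 9.5.1.1, per the file headers. The labels put the sample RNA in Cy3 and the reference RNA in Cy5 on every array, with no dye swap, so a dye effect that is the same on all arrays cancels between groups. The reference was, per the labels' protocols, RNA pooled from 11 cultured cell lines and mixed 2:1 with ES cell RNA. The deposited intensity values of the scanner files (mean signal and median background per spot and channel) carry no normalization. The deposited processed intensities had been background-subtracted and dye-normalized by the extraction software, per the file headers. The deposited log10 ratios in the same files are of Cy5 over Cy3. The authors' value table holds log10 values for 25030 of the 42006 probes. Column by column, after centring each probe, it matched minus the deposited log10 ratio (r of 0.99927 to 0.99997 over 14654 probes clear of the floor), so its direction is sample over reference with 1 constant added per probe. The medians of its columns were 2.24 to 2.32, dim probes lie at a floor near 1, and where the constant, and so the centring, comes from stays unknown. No step between scanner files and value table is given in the sources used here.

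Mean signals were corrected for background with normexp (offset 50) in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table. Log ratios were normalized within each array by loess, with control spots at weight 0, and the sign was set to log2 of sample over reference. Control spots and the 1 to 24 spots per array flagged as outliers were then left out, and spots of 1 probe were averaged. A probe was tested if its Cy3 spot was well above background on both arrays of at least 1 group, which kept 31053 of 42006 probes (73.9%). Saturated Cy3 spots numbered 0 on every array. Each group mean was fitted over all 14 arrays with 7 residual degrees of freedom (5.33 added by the prior), so that groups of 2 share one estimate of the spread. Contrasts were tested with eBayes, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes, with a second count that also asks for a 2-fold change. In simulated data for RA 48 h against control day 3, run on 31053 probes, the steps recovered 100% of 66 probes changed by a log2 of 2, 97% of 67 changed by 1 and 74.6% of 67 changed by 0.5, with 15 false calls among 30853 unchanged probes (7.65% of the calls). For passage 10 against standard day 3 the shares were 100%, 95.5% and 70.1%, with 6 false calls. The simulation drew independent noise around values already normalized and changed few probes. It thus covers the fit and the tests, and not background correction, normalization, slide effects or correlated probes.

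Groups, comparisons, tests, the rule for named genes, 24 gene lists with 657 gene symbols, and most alternatives were fixed before the data were examined. The scanner files give probes only an identifier and a sequence, and the reference table of gene names holds no sequences. Of the 657 symbols 0 were found among the probe names, so the gene lists could not be tested, genes could not be named and probes of 1 gene could not be joined. Each probe was therefore tested on its own. The rule for named genes asked for the 10 largest rises and the 10 largest falls per comparison among those past the threshold whose arrays did not overlap between the groups, without probes lacking a symbol, and for members of the gene lists and 11 fixed genes. As every probe lacks a symbol, the first part was applied without that clause and kept to 2 rises and 2 falls, which was decided after the data were seen, and the other parts could not be applied. All named probes were well above background on both arrays of both groups compared.

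In place of gene lists, sets of probes were defined on some arrays and tested on others with camera (preset correlation 0.01, and again with an estimated one) and fry, a choice made after the data were seen. The sets were the probes changed at least 2-fold by RA or LY294002 at 48 h or in day 7 colonies, and the probes at least 2-fold above (ES-side) or 4-fold below (reference-side) the reference on both arrays of a group. Reference-side and ES-side probes also had to be above background in Cy5 on all arrays. Adjustment was over all 28 set tests. Camera compares a set with all other probes, and fry asks whether its probes move one way on balance.

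The arrays lay on 6 slides scanned on 4 days. Control day 3 and RA 48 h shared slide 5. LY294002 48 h lay on slide 6, day 4 colonies on slide 4 and day 7 colonies on slide 1. Standard day 3 and passage 10 each had 1 array on slide 2 and 1 on slide 3, with the same replicate number on the same slide. There the same-numbered arrays deviated together (r = 0.254 across probes), and the number is the slide. In the other comparisons r was -0.0865 to 0.113, and no label ties their numbers. Slide and scan day were also fitted as random blocks (consensus correlation -0.0338 and 0.0303). Slides 1, 4 and 6 each held arrays of 1 group only, so the slide block can neither show nor correct a slide effect in comparisons of those groups. The highest share of equal Cy3 values between any 2 arrays was 0.019%, so no array repeated another. The other alternatives were no background subtraction, the processed signals, median centring, Aquantile scaling (which leaves log ratios unchanged and so tested nothing), Cy3 alone, the value table, 2 other filters on dim probes, an intensity trend with robust estimation, smaller fits, other baselines and leaving out each array.

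Some labels disagree. The series' design says that colonies were picked by hand on day 4 and day 7, while an extraction protocol for picked and pooled colonies is attached to 12 arrays, untreated ones included, and that of the day 7 arrays names 1 well. The cell line of the day 7 arrays is given as MC1, called intact in their titles, while their source label has the prefix ZE of the sublines without a number, so their exact origin is not certain. The source label of control day 3 names growth factors, while its treatment text gives standard medium with LIF, so whether factors were added is unknown. The LY294002 dose of 10 nM is given as the label has it. This inhibitor is commonly used in the micromolar range, so the unit, and with it the strength of the treatment, is in doubt.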

Results

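RNA from mouse embryonic stem (ES) cells was hybridised to 14 Agilent 2-colour oligonucleotide arrays, 2 arrays in each of 7 groups. The cells were of the line MC1 and its sublines MC1-ZE3 and MC1-ZE16, and each array carried the RNA of 1 sample labelled with Cy3 beside a common reference labelled with Cy5. Retinoic acid (RA), a vitamin A derivative, drives ES cells out of the undifferentiated state, and LIF, the cytokine in the medium of these cultures, helps to hold them in it. LY294002 inhibits phosphoinositide 3-kinase. The groups were MC1-ZE3 cells grown for 3 days as the control of a treatment experiment (control day 3), the same subline after 48 h in 50 nM RA (RA 48 h) and after 48 h in LY294002 (10 nM by the label, a unit open to doubt), untreated MC1-ZE3 cells in standard culture (standard day 3), colonies of cells called pluripotent in the series' design, picked by hand on day 4 in 50 nM RA from MC1-ZE16, such colonies picked on day 7 from MC1, and MC1-ZE3 cells exposed to RA for 7 days and then grown for 10 passages without it (passage 10). Between 56.1% and 75.1% of the probes on an array were well above background in Cy3, and the median Cy3 signal was 1.88 to 2.96 times its local background. The mean share was 73.9% in control day 3, 71.8% in RA 48 h, 67.2% in LY294002 and 66.2% in day 7 colonies. It was 58.5% in day 4 colonies, 58.0% in standard day 3 and 57.3% in passage 10. Whether this difference in brightness shaped the balance of rises and falls was not tested. Replicate arrays correlated at r = 0.973 to 0.993 across probes, which are not independent replicates. The number of arrays limits the precision. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Of 42006 probes, 31053 were tested. The files pair no probe with a gene, so probes are given by their identifier and their 60-base sequence.

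The first question was what 48 h of RA changed in these cells. Against control day 3, 840 probes rose and 278 fell at least 2-fold (1293 and 850 with Agilent's processed signals, 1073 and 601 with the authors' value table) among 11907 probes past limma's threshold, of which 6962 rose and 4945 fell. Probe Z00005024-1 (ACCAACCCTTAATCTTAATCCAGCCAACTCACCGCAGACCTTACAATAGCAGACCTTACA) went from a log2 ratio to the reference of 0.41 ± 0.16 (SD, n = 2) to 5.19 ± 0.05, a log2 rise of 4.79 (SE 0.25, limma adjusted p = 2.05e-08), or 27.7-fold. Probe Z00036124-1 (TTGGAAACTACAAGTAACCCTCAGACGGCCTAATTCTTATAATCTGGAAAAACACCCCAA) rose by 4.27 (SE 0.12, limma adjusted p = 2.69e-10), yet at -2.70 it stayed below the reference. Probe Z00004978-1 (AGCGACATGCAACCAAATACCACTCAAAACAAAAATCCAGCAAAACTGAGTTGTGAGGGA) fell by 2.76 on the log2 scale (SE 0.06, limma adjusted p = 6.83e-11), and Z00025932-1 (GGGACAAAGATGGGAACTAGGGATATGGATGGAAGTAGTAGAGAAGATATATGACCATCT) fell by 2.65 (SE 0.10, limma adjusted p = 2.36e-09). Both control and RA arrays lay on 1 slide, so this comparison is free of differences between slides.

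Probes brighter in ES cells than in the reference moved down at 48 h of RA, and probes dimmer in them moved up. The reference held RNA of 11 other cell lines mixed 2:1 with ES cell RNA, so a probe far brighter in the cells than in the reference measures RNA that these cells hold more of than the mixture does. On both standard day 3 arrays 1351 probes were at least 2-fold above the reference (ES-side probes) and 1302 were at least 4-fold below it (reference-side probes). Neither set was chosen on the arrays compared here. But control day 3 is the same subline, and 763 of the ES-side probes were also ES-side there. Probes chosen as high or low thus tend to be so in this baseline. A fall of ES-side probes, or a rise of reference-side ones, can come in part from that choice. Of the ES-side probes 699 fell and 183 rose, with a median log2 change of -0.26 (camera adjusted p = 2.84e-16; adjusted p = 0.00301 with an estimated correlation). Of the reference-side probes 756 rose and 56 fell, with a median of 0.37 (camera adjusted p = 7.03e-20), a call that was lost with an estimated correlation (adjusted p = 0.174). Without loess, with log ratios only centred on their median, 2371 probes rose and 2908 fell, and with Agilent's processed signals 4015 rose and 4921 fell, so the balance of small rises and falls depended on the scaling.

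With LY294002 more probes fell than rose at least 2-fold, by a margin that depended on the scaling. Against control day 3, 1783 probes fell and 440 rose by this much (1243 and 1107 with median centring, 3658 and 1236 with Agilent's processed signals), among 16322 past limma's threshold (7595 rose and 8727 fell). Probe Z00059689-1 (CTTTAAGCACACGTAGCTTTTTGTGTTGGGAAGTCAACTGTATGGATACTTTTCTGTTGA) rose by 2.69 on the log2 scale (SE 0.12, limma adjusted p = 1.24e-09) and Z00070436-1 (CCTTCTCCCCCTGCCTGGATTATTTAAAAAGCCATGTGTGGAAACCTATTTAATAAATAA) by 2.56 (SE 0.09, limma adjusted p = 1.39e-10). The same Z00070436-1 fell by 1.51 at 48 h of RA. Probe Z00031029-1 (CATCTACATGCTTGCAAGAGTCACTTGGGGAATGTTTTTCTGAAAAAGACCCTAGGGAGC) fell by 4.94 with LY294002 (SE 0.14, limma adjusted p = 2.99e-11) and rose by 2.87 with RA (limma adjusted p = 1.09e-08). Probe Z00074771-1 (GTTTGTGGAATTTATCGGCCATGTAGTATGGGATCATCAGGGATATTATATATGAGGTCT) fell by 4.91 (SE 0.08, limma adjusted p = 4.66e-13). Of the ES-side probes 695 fell and 335 rose (median -0.27, camera adjusted p = 2.85e-05, and 0.0363 with an estimated correlation). As at 48 h of RA, where the median was -0.26, part of this fall can come from the choice of probes. Of the reference-side probes 496 fell and 219 rose (median -0.10, camera adjusted p = 0.0106, but 0.761 with an estimated correlation). With median centring the reference-side median was 0.17, with 355 fallen and 474 risen (camera adjusted p = 0.759). That scaling also raised the median of all probes, to 0.12.

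The choice of untreated cells mattered for LY294002. Against standard day 3, 983 probes fell and 469 rose at least 2-fold. Of the 1783 probes lowered against control day 3, 1397 were also lower than in standard day 3, 631 of them at least 2-fold, and the median log2 change of all 1783 was -0.69 in place of -1.46. Of the 440 raised probes 344 were also higher than in standard day 3. The LY294002 arrays that chose these probes are also in the comparison with standard day 3, so part of this overlap was built in. The fall of Z00074771-1 shrank to a log2 change of -0.46 (limma adjusted p = 0.000264), the fall of Z00031029-1 to -3.25 and the rise of Z00059689-1 to 1.11. The LY294002 arrays were alone on their slide, so slide and treatment cannot be told apart, while control day 3 was scanned on the same day. With median centring 7236 probes rose and 3929 fell against control day 3, so the direction of the small changes again depended on the scaling.

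RA and LY294002, given for the same time, were also set directly against each other. Here 2294 probes were at least 2-fold higher and 344 lower with RA, a balance that turned to 1420 higher and 1716 lower with median centring, among 16643 past limma's threshold (9564 higher and 7079 lower; 4554 and 9543 with median centring, 7008 and 9684 with the Cy3 channel alone). The log2 changes of both treatments against control day 3 correlated at r = 0.186 across probes, which are not independent replicates. Unchanged groups that share those control arrays gave r = 0.50 over 100 simulations. That value follows from the sharing alone, as the simulated groups held only noise. The observed r also holds real changes, so these 2 values of r cannot be compared. The covariance was 0.045 against 0.0046 simulated. With standard day 3 as the baseline of LY294002, so that no array was shared, r was 0.158. Of the 278 probes lowered at least 2-fold at 48 h of RA (RA-lowered) 202 were lower and 28 higher with LY294002 than in standard day 3 (median -0.83, camera adjusted p = 3.48e-26, and 0.03 with an estimated correlation). Of the 840 probes raised as much (RA-raised) 267 were lower and 224 higher (median -0.07, camera adjusted p = 0.316, fry adjusted p = 0.0439). The sign of this median turned in the set chosen by adjusted p alone (median 0.07, 2424 higher and 1584 lower, camera adjusted p = 0.0188). It also turned with median centring (median 0.09, 202 higher and 96 lower, camera adjusted p = 0.0329). That scaling raised the median of all probes too, to 0.12 for LY294002 against control day 3, so its turn need not set RA-raised probes apart.

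**Figure D1:**
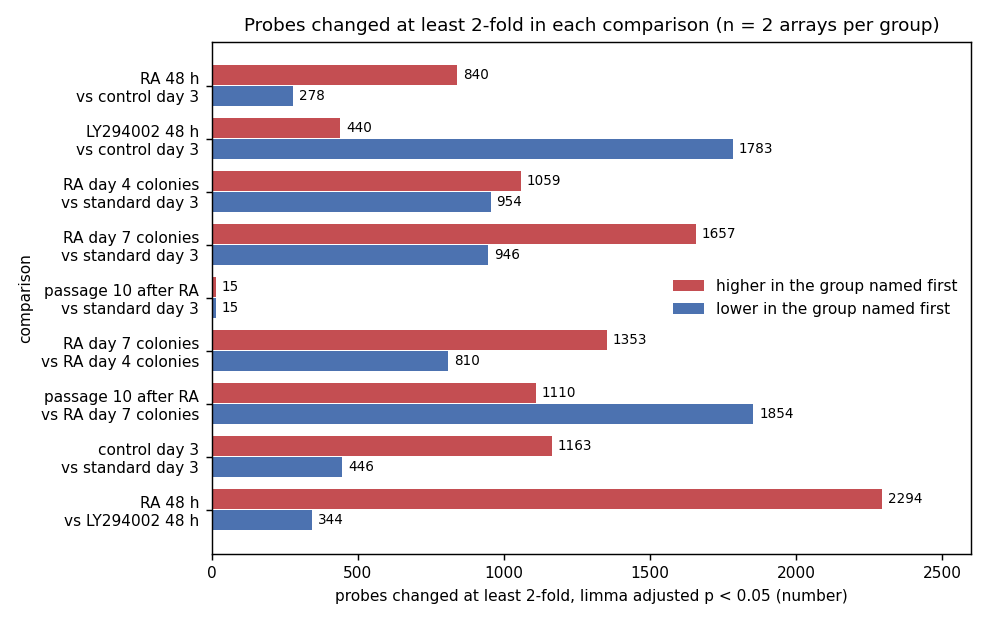
The bars give the number of probes, of 31053 tested, that differed at least 2-fold past limma's adjusted threshold in each of 9 comparisons of 2 arrays with 2 (horizontal axis, number of probes; red, higher in the group named first; blue, lower). Passage 10 against standard day 3 had 15 higher and 15 lower, and RA 48 h against LY294002 48 h had 2294 higher and 344 lower.

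The picked colonies were compared with standard day 3 cells to see how far picked cells resembled untreated ones. Each kind of colony lay alone on 1 slide and came from other cells than standard day 3. Slide and cells thus cannot be told apart from RA, and the spread between replicate colony arrays holds no difference between slides. The 2 untreated groups, also on different slides, differed at least 2-fold in 1609 probes. On day 4, 1059 probes were at least 2-fold higher and 954 lower (3333 and 2143 with Agilent's processed signals), among 15049 past limma's threshold (7830 rose and 7219 fell). Probe Z00055038-1 (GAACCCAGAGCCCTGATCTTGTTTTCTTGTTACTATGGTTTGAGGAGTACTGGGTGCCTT) rose by 4.71 on the log2 scale (SE 0.13, limma adjusted p = 6.41e-11), or 26.2-fold, and Z00075242-1 (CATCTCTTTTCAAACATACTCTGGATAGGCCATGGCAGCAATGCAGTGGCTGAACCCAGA) by 4.45 (SE 0.14, limma adjusted p = 1.43e-10). At 48 h of RA Z00055038-1 had risen by 0.68. The end of the sequence of Z00075242-1 matches the start of that of Z00055038-1, and in day 7 colonies they lay at 1.36 and 1.32. Both may thus measure the same RNA and need not be separate rises. With median centring 3449 probes rose and 4016 fell, and at least 2-fold 844 rose and 1012 fell. Probe Z00025439-1 (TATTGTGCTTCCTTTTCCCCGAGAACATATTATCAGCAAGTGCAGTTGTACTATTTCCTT) fell by 4.62 (SE 0.11, limma adjusted p = 1.73e-11) and Z00048598-1 (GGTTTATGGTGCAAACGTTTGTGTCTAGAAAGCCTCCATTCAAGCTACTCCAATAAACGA) by 4.30 (SE 0.15, limma adjusted p = 2.46e-10).

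On day 7, 1657 probes were at least 2-fold higher than in standard day 3 cells and 946 lower, 2603 in all against 2013 on day 4, among 16593 past limma's threshold (8809 rose and 7784 fell). With median centring 7153 rose and 2676 fell (2169 and 589 at least 2-fold), and with Agilent's processed signals 14494 rose and 3966 fell (5964 and 1317 at least 2-fold). Probe Z00000270-1 (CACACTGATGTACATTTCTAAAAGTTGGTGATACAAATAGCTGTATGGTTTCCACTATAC) rose by 7.47 on the log2 scale (SE 0.08, limma adjusted p = 1.15e-14), or 177-fold, and Z00015331-1 (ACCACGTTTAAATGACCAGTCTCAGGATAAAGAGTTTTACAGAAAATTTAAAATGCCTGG) by 6.14 (SE 0.08, limma adjusted p = 6.11e-14). With control day 3 as the baseline these rises were 4.44 and 3.44. Against control day 3 the order of the 2 kinds of colony turned, with 1155 probes at least 2-fold higher and 1837 lower on day 4, and 1132 higher and 1134 lower on day 7. Probe Z00026394-1 (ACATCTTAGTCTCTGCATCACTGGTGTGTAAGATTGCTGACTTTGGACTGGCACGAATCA) fell by 4.44 (SE 0.13, limma adjusted p = 3.32e-11), and Z00048598-1 fell by 4.17 (SE 0.15, limma adjusted p = 1.66e-10). Between day 4 and day 7 colonies, 1353 probes were at least 2-fold higher and 810 lower on day 7 (4769 and 1298 with Agilent's processed signals), among 16402 past limma's threshold (8515 higher and 7887 lower; 7777 and 2521 with median centring, 12065 and 4581 with Agilent's processed signals). By their cell line labels day 4 colonies came from the subline MC1-ZE16 and day 7 colonies from MC1 itself, so day and cells cannot be told apart.

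**Figure D2:**
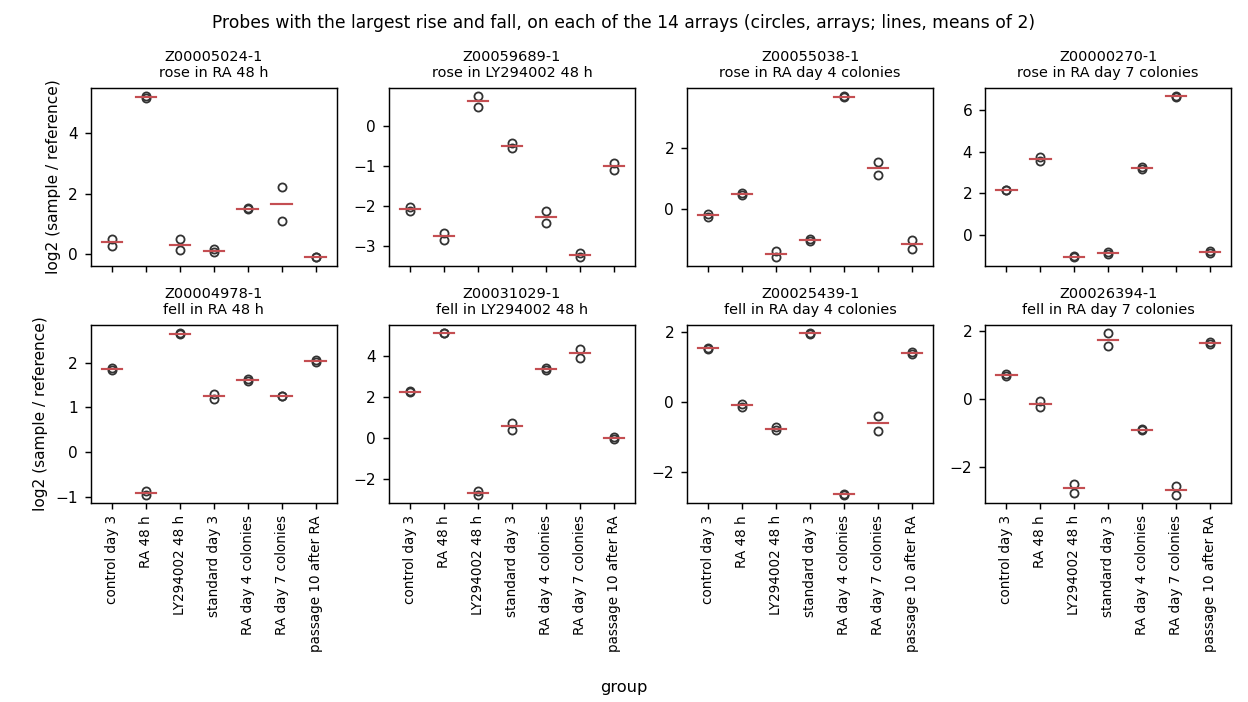
Each panel shows the log2 ratio of sample to reference (vertical axis) of 1 probe on all 14 arrays (circles), by group (horizontal axis), with the mean of each pair of arrays as a line; panels are the probes with the largest rise (top) and fall (bottom) in 4 comparisons. Z00000270-1 lay at 6.63 in day 7 colonies and at -0.84 in standard day 3, and at 2.19 in control day 3.

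Probes changed by 48 h of RA were mostly changed in the same direction in the colonies. Of the 840 probes raised at least 2-fold at 48 h, 469 rose and 142 fell in day 4 colonies (median log2 change 0.36, camera adjusted p = 2.74e-09), a call that was lost with an estimated correlation (adjusted p = 0.141). In day 7 colonies 622 of them rose and 96 fell (median 0.81, camera adjusted p = 1.3e-21; adjusted p = 0.0363 with an estimated correlation). Of the 278 lowered probes 228 fell and 20 rose on day 4 (median -1.06, camera adjusted p = 1.4e-36; adjusted p = 0.0149 with an estimated correlation), and 201 fell and 33 rose on day 7 (median -0.84, camera adjusted p = 4.73e-24; adjusted p = 0.0321 with an estimated correlation). In both kinds of colony 427 raised and 185 lowered probes had moved in the direction of 48 h. Cells in LY294002, without RA by their labels, had 202 of the 278 lowered probes lower than standard day 3 and 28 higher (median -0.83). The fall of RA-lowered probes was thus not particular to cells given RA. Of the 840 raised probes 224 were higher and 267 lower with LY294002 (median -0.07). The log2 changes at 48 h correlated with those of day 4 colonies at r = 0.386 and with those of day 7 colonies at r = 0.421 across probes, with no array shared. At least 2-fold rises shared by 48 h and day 4 numbered 221 where 28.7 would be shared by independent lists, and those shared with day 7 numbered 356 where 44.8 would be. Shared falls numbered 148 on day 4 (8.54 if independent) and 121 on day 7 (8.47). LY294002 against standard day 3 shared 55 rises with 48 h of RA (12.7 if independent) and 117 falls (8.8). An excess over independent lists was thus not particular to cells given RA.

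The change from 48 h of RA, against control day 3, differed from the change in the colonies, against standard day 3. Since these baselines differ from each other, and the colonies were picked and came from other cells of the line, the difference cannot be laid to RA alone. The test of the difference in limma found 12026 probes for day 4 against 48 h, 816 of them at least 2-fold more positive in the colonies and 1268 more negative (2998 and 1947 with Agilent's processed signals), and 13298 probes for day 7 against 48 h, with 1147 and 1113 (5404 and 1070 with Agilent's processed signals). Over all sizes 5503 were more positive and 6523 more negative for day 4 (7435 and 3991 with Agilent's processed signals), and 6402 and 6896 for day 7 (12363 and 2437 with Agilent's processed signals, 5386 and 1539 with median centring). Z00005024-1, raised by 4.79 at 48 h, was up by 1.38 on day 4 and by 1.53 on day 7.

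ES-side probes were tested in the colonies with 2 definitions, and the difference between these was not tested. With 1521 probes at least 2-fold above the reference on both passage 10 arrays, 999 fell and 212 rose on day 4 (median -0.50, camera adjusted p = 7.42e-22) and 1090 fell and 189 rose on day 7 (median -0.60, camera adjusted p = 1.09e-25), and adjusted p = 0.00229 for each with an estimated correlation. With 2102 probes above the reference on both control day 3 arrays, 898 fell and 670 rose on day 4 (median -0.11, camera adjusted p = 0.0512, which passed the threshold downward under 4 alternatives), and 750 fell and 783 rose on day 7 (median 0.02 and mean 0.07, against a downward camera test with adjusted p = 0.817). With median centring this last median was 0.32 (camera adjusted p = 0.000188), where the median of all tested probes was 0.08. With Agilent's processed signals it was 0.19 (camera adjusted p = 0.00449), where that of all tested probes was 0.38. The set's median thus lay above that of all probes with the first scaling and below it with the second. Neither definition shared an array with the comparison. But passage 10 lay on the slides of standard day 3, and 1160 of its ES-side probes were also ES-side in standard day 3. Probes chosen as high or low in passage 10 thus tend to be so in the baseline too. A fall of its ES-side probes, or a rise of its reference-side ones, can come in part from that choice. The same holds for the control day 3 definition, of which 763 ES-side probes were also ES-side in standard day 3. Reference-side probes of passage 10 rose more often than they fell, 541 against 177 of 1351 on day 4 (median 0.18, camera adjusted p = 4.11e-05; adjusted p = 0.57 with an estimated correlation) and 716 against 277 on day 7 (median 0.31, camera adjusted p = 6.83e-07; adjusted p = 0.464 with an estimated correlation).

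**Figure D3:**
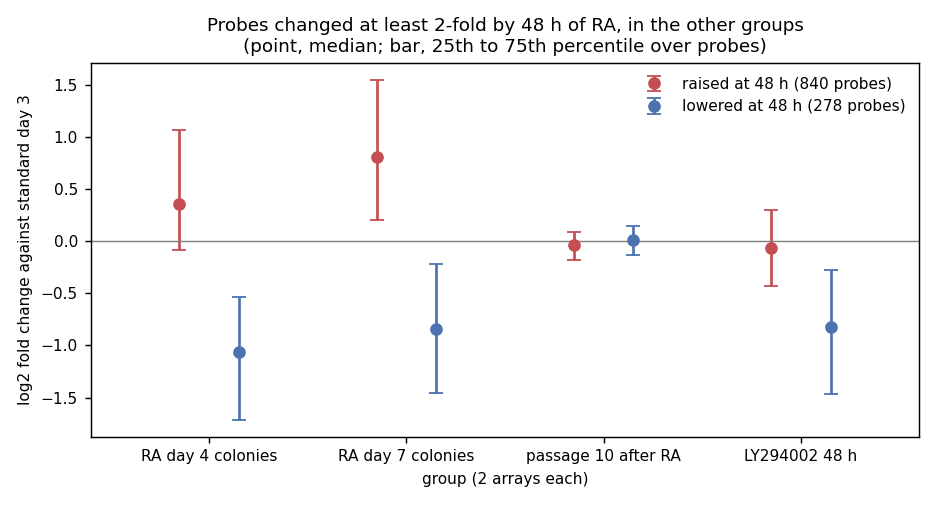
The points give the median log2 fold change against standard day 3 (vertical axis) of the 840 probes raised and the 278 probes lowered at least 2-fold by 48 h of RA, in 4 other groups of 2 arrays (horizontal axis), and the bars run from the 25th to the 75th percentile over probes. The medians of raised probes lie above 0 and those of lowered probes below it in both colony groups, where the bar of raised probes on day 4 starts at -0.08, and passage 10 lies at -0.04 and 0.01. For LY294002 48 h the median of raised probes is -0.07 and that of lowered probes -0.83.

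Cells grown for 10 passages after RA differed in few probes from standard day 3 cells, which lay on the same slides. Of 1061 probes past limma's threshold 514 rose and 547 fell, and 15 rose and 15 fell at least 2-fold (81 and 117 with Agilent's processed signals, 81 and 75 with the authors' value table). In all, 5335 probes had an unadjusted p under 0.05. Probe Z00026289-1 (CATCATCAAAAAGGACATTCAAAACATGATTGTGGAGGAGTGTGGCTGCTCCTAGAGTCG) rose by 1.89 on the log2 scale (SE 0.09, limma adjusted p = 8.53e-07) and Z00070458-1 (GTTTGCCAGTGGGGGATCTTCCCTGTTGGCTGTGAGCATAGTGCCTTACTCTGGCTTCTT) by 1.68 (SE 0.10, limma adjusted p = 2.35e-06). Probe Z00078103-1 (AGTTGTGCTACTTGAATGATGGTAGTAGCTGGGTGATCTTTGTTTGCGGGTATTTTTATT) fell by 1.82 (SE 0.12, limma adjusted p = 5.9e-06) and Z00014876-1 (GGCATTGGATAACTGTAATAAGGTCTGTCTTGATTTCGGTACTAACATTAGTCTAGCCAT) by 1.55 (SE 0.10, limma adjusted p = 4.45e-06). Each of 2 slides held 1 array of each group, and the differences within each slide correlated at r = 0.511 over all probes, which are not independent replicates. With the slide as a random block 1027 probes passed. Against control day 3, on another slide, 751 probes were at least 2-fold higher in passage 10 and 1494 lower. Day 7 colonies had 1132 higher and 1134 lower against that baseline. The small difference thus holds for standard day 3 alone. For passage 10 against standard day 3, the count past the threshold depended on single arrays and on the scaling, and it also changed with the baseline. It was 263 without passage 10 replicate 1, 379 without passage 10 replicate 2, 304 without standard day 3 replicate 2, 540 with these 4 arrays alone, 37 with median centring, 17897 with control day 3 as the baseline and 649 with Agilent's processed signals (235 rose and 414 fell).

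In passage 10 cells the probes changed by RA lay near 0. Of the 840 RA-raised probes 29 were higher and 75 lower than in standard day 3 (median -0.04, camera adjusted p = 0.00212; adjusted p = 0.464 with an estimated correlation and 0.137 with Agilent's processed signals), and of the 278 RA-lowered probes 23 were higher and 16 lower (median 0.01, camera adjusted p = 0.669). The 1132 probes raised at least 2-fold in day 7 colonies over control day 3 held 44 higher and 50 lower (median 0.0041 and mean -0.00038, camera adjusted p = 0.788), and the 1134 probes lowered there held 59 higher and 101 lower (median -0.04, camera adjusted p = 0.00943; adjusted p = 0.281 with an estimated correlation, 0.247 with Agilent's processed signals and 0.0542 with fry). The log2 changes at 48 h and at passage 10 correlated at r = -0.0179 across probes. Against day 7 colonies, passage 10 cells had 1110 probes at least 2-fold higher and 1854 lower (1445 and 6611 with Agilent's processed signals), among 17302 past limma's threshold (8273 higher and 9029 lower; 3090 and 7617 with median centring, 4305 and 14870 with Agilent's processed signals).

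Both groups of untreated cells, of the same subline and the same day of culture by their labels, differed from each other. The source label of control day 3 also names growth factors, which its treatment text does not, so its medium is not certain. Control day 3 had 1163 probes at least 2-fold higher and 446 lower than standard day 3 (4483 and 837 with Agilent's processed signals), among 16742 past limma's threshold (9131 higher and 7611 lower; 6928 and 2432 with median centring, 11641 and 4452 with Agilent's processed signals). Z00074771-1 lay at 0.07 in control day 3 and at -4.37 in standard day 3. Control day 3 arrays correlated with those of standard day 3 at a mean r of 0.854 across probes, where passage 10 arrays did so at 0.978. The groups lay on different slides and were scanned on different days. Control day 3 arrays were also brighter in Cy3, with a median signal of 2.86 times background against 2.09 in standard day 3. The part this played in the excess of higher probes was not tested.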

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

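All tests of explanations in this part were chosen after the results were seen. The change at 48 h of RA differed from that in the colonies by limma's test of the difference itself, with baselines, cells of origin and picking that differed too. For day 4 colonies 12026 probes passed the threshold, and for day 7 colonies 13298 did.

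The colonies carried part of the 48 h change. The RA-lowered probes also lay lower with LY294002, without RA, than in standard day 3 (median -0.83), so their fall is not particular to RA. A mixture of untreated cells and cells in the 48 h state was first weighed by the share of 48 h cells that each probe needs, with medians of 0.157 (RA-raised, quartiles -0.0312 and 0.548) and 0.901 (RA-lowered, 0.518 and 1.14) on day 4 and 0.416 (0.0945 and 0.924) and 0.766 (0.24 and 1.07) on day 7, which overlapped and decided nothing, and next by a count of RA-raised probes below standard day 3, which was dropped since control and standard day 3 differ. The last test took 820 probes raised at 48 h over both untreated groups and counted those below both in the colonies. Day 4 had 94, 13 of them at least 2-fold below, where 29.9 false calls are allowed. The allowance is a fixed share of the 598 that passed the test against standard day 3, not of those below both. The count was 136 against 39.2 with processed signals and 46 against 16.4 with median centring. But both untreated groups were MC1-ZE3 cells on other slides, with 0 untreated arrays of MC1-ZE16. An offset of subline or slide could put probes below both, so the test cannot decide on a mixture on day 4. On day 7 the test found 64 where 35.2 are allowed, but 47 against 49.8 with processed signals and 21 against 24.0 with median centring. The mixture stays open there too. Standard day 3 samples that stand apart from the passage 10 samples of their slides are argued against by a median log2 change of -1.06 (quartiles -1.78 and -0.46) of the RA-lowered probes on day 4 with passage 10 as the baseline, which leaves open a trait of those slides or cultures that both groups share, while the cells of origin cannot be told apart from treatment, with 0 untreated arrays of MC1 or MC1-ZE16, and the time in RA and the picking stay open as untested.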

How the results depend on the processing

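The scan-day block and every alternative for the probe sets were chosen after the data were seen. Of 190 counts of calls under alternatives 169 lay within 1.5 times the value given first. The value was below this for median centring in place of loess with 5279 (RA 48 h against control), 7465 (day 4 against standard), 9829 (day 7 against standard), 37 (passage 10 against standard), 10298 (day 7 against day 4), 10707 (passage 10 against day 7), 9360 (control against standard), 4065 (day 4 change minus 48 h change) and 6925 (day 7 change minus 48 h change). For the authors' value table, which holds fewer probes, it was 7576 (RA 48 h), 10754 (LY294002), 11059 (day 7), 10889 (day 7 against day 4), 10796 (control against standard) and 8402 (day 7 change minus 48 h change). Passage 10 against standard had 649 with Agilent's processed signals, 540 with 4 arrays alone and 17897 against control day 3. Leaving out 1 array at a time gave 263 to 934 for passage 10 against standard, where the lone array of a group is assumed to vary like the other groups, and kept all other counts within 1.5 times. Except where fewer probes or arrays were used, the cause was not tested.

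All 349 values of named probes under 29 alternatives kept their direction and their side of the threshold, and so did 310 of 366 values of probe sets under 23 alternatives, by the sign of their median. Aquantile scaling is left out of these numbers, since it cannot change a log ratio. For the named probes, chosen as the largest changes, keeping direction and side was close to fixed in advance. Their sizes did move: Z00074771-1 went from -4.91 with LY294002 against control day 3 to -0.46 against standard day 3. Processed signals shifted the median of all probes by a log2 of 0.37 in day 7 against standard, 0.26 in day 7 against day 4, -0.39 in passage 10 against day 7, 0.23 in control against standard, 0.21 and 0.46 in the differences from 48 h, -0.11 in RA 48 h and 0.10 in day 4 against standard. Median centring shifted it by 0.11 for LY294002, -0.14 for RA 48 h against LY294002 and 0.11 for the day 7 change minus 48 h change.

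For the sets, RA-raised probes in day 4 colonies (median 0.36) lost their call with an estimated correlation, and so did reference-side probes in RA 48 h (median 0.37). Probes lowered in day 7 colonies lost theirs in passage 10 with an estimated correlation, processed signals and fry. RA-raised probes in passage 10 lost theirs with an estimated correlation and with fry (median -0.0374), processed signals (-0.0723) and the value table (0), and turned to 0.0084 when chosen by adjusted p alone. Over arrays left out their median was -0.06 to -0.02. RA-raised medians with LY294002 turned sign, to 0.0757 (processed signals) and, past the threshold, 0.0926 (median centring) and 0.0685 (chosen by adjusted p alone). LY-raised ones on day 7 were 0.11 (processed signals) and 0.05 (median centring), below the 0.38 and 0.08 of all probes. Others were 0.17 (median centring) for reference-side probes with LY294002 and -0.0047 (Cy3 alone) for those of control on day 4. With no call under either setting, signs also turned to -0.0058 (chosen by adjusted p alone) for RA-lowered probes in passage 10, to -0.0059 (processed signals) and -0.0113 (above background on all arrays) for day 7-raised probes there, to 0.0065 (median centring) for ES-side probes of control on day 4, and on day 7 to -0.0485 (Cy3 alone) and -0.109 (value table) for these and to -0.0374 (no filter) for reference-side probes of control.

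With the replicate number as a block, a replicate block that for passage 10 against standard is also the slide, this comparison gave 1179 calls. Same-numbered arrays of other groups share only a number, and the block gave 11212 for RA 48 h, 16145 for LY294002, 14917 for day 4, 17069 for day 7, 16674 for day 7 against day 4, 17543 for passage 10 against day 7, 16500 for control against standard and 16427 for RA 48 h against LY294002, all within 1.5 times. For the differences from 48 h the replicate block was not fitted, and slide and scan day blocks were. Alternatives that need gene names (probes of a gene averaged, gene lists with an estimated correlation or with fry) were not run, and testing every probe on its own is what was done. Signal over background limits the dim probes: 21861 of the 31053 tested probes were above background on all arrays.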

Other observations

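Sequence gave a check on single probes. Among the tested probes 1038 pairs shared a stretch of 20 bases with each other and with no other tested probe. Their log2 changes correlated at r = 0.949 for RA 48 h, 0.947 for LY294002, 0.941 for day 4 colonies, 0.943 for day 7 colonies and 0.85 for passage 10, where a random partner gave between -0.0063 and 0.0282. Where both probes of a pair passed limma's threshold they went the same way in 368 of 369 pairs for RA 48 h, 552 of 557 for LY294002, 503 of 507 for day 4, 566 of 572 for day 7 and 39 of 39 for passage 10. The pairs lie on the same arrays and are no further replicates.

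Probes changed by LY294002 against control day 3 were followed in the colonies. Of the 440 raised probes 199 were lower and 114 higher on day 4 than in standard day 3 (median -0.18, camera adjusted p = 0.00051, but 0.0905 with an estimated correlation and 0.127 in the set chosen by adjusted p alone). On day 7, 215 were lower and 116 higher (median -0.20, camera adjusted p = 0.00118, but 0.106 with an estimated correlation). With processed signals the day 7 median was 0.11 (405 higher and 303 lower, camera adjusted p = 0.00018), where the median of all probes was 0.38. With median centring it was 0.05, where that of all probes was 0.08. The sign thus turned under scalings that raised all probes, and the set's median stayed below theirs. Of the 1783 lowered probes 750 were higher and 566 lower on day 4 (median 0.09, camera adjusted p = 0.155; adjusted p = 0.0364 with median centring and 0.00102 with fry), and 816 higher and 576 lower on day 7 (median 0.15, camera adjusted p = 0.0923; adjusted p = 0.0122 with median centring, 0.0222 with no filter and 8.82e-05 with fry). Probes on the ES side of control day 3 held 169 lower and 60 higher of 2102 in passage 10 (median -0.05, camera adjusted p = 4.01e-05; adjusted p = 0.0363 with an estimated correlation). Those on its reference side held 48 lower and 51 higher of 1259 there (median 0.04, camera adjusted p = 0.083; adjusted p = 0.0217 with no background subtraction and 0.0352 with no filter), 173 lower and 387 higher in day 4 colonies (median 0.12, camera adjusted p = 0.0139; lost under 6 alternatives, with adjusted p = 0.78 with an estimated correlation, 0.652 with processed signals, 0.616 and a median of -0.0047 with Cy3 alone, 0.356 with the value table, 0.161 with median centring and 0.0536 with fry) and 363 lower and 501 higher in day 7 colonies (median 0.01, camera adjusted p = 0.157), a shift that passed the threshold under 6 alternatives, all upward.

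All tests of explanations below were chosen after the results were seen. The 2 untreated groups differed by far more than replicate arrays did. Between an array of control day 3 and one of standard day 3 at least 1598 probes lay 2-fold apart, against at most 60 between replicate arrays of any group, so array-to-array variation as measured by these replicates is argued against. A difference in the Cy5 reference is argued against, as Cy5 carried a median of 1.2% of the 2-fold differences (quartiles -13.3% and 14.3%), but this says nothing of slide or scan effects on Cy3, and slide and group cannot be told apart here. Culture, medium or RNA preparation in the 2 experiments cannot be told apart from the groups either: the LY294002 arrays showed a median share of 0.217 of the difference (quartiles -0.162 and 0.612), and they were also treated. Against passage 10, on the slides of standard day 3, probes higher in control day 3 had medians of 1.42 in RA 48 h, 0.84 in day 7, 0.44 in day 4 and 0.26 in LY294002 arrays (lower ones -1.18, -0.89, -0.42 and -0.71), so standard day 3 and passage 10 standing apart together stays open too, and a test of a direction shared by control day 3 and day 7 colonies was dropped for this reason.

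The falls with LY294002 against control day 3 were weighed against 2 technical accounts. If control day 3 standing apart were the whole account, the LY-lowered probes would lie near 0 against standard day 3. Their median was -0.69 (quartiles -1.29 and -0.31). But the same LY294002 arrays chose these probes and enter this median, which draws it below 0 by an amount not measured. The test thus cannot tell whether control day 3 accounts for all or part of the fall. Cy5 carried a median of -3.5% of it, which argues against a difference in the Cy5 reference and says nothing of slide or scan effects on Cy3. Slide and treatment cannot be told apart, and an effect of these cultures other than the inhibitor stays open.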
